A study of Mus musculus with 4 samples.

How the data were processed

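Each capture of the 10x 3′ v3 kit gave a gene expression library and a hashtag library, so the 4 deposited samples are 2 captures of 2 populations each. Hashtags 1 and 2 marked BFP+ and BFP− cells of untreated mice, and hashtags 3 and 4 those of MC903-treated mice, per the labels. The untreated and MC903 captures were sequenced on different lanes, per the labels' protocols. How many mice went into a pool is not given in the sources used here.

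The deposited values are UMI counts per gene or hashtag and barcode, made with Cell Ranger 3.1.0 per the file headers and aligned to GRCm38 per the submitters' processing notes. Each matrix has 22631 gene rows, among them the BFP reporter. Empty droplets were not used here, so free RNA was estimated from cell types that lack a gene.

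Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept (8422 of 9520 untreated and 5636 of 6316 after MC903). The MC903 capture had a median of 2299 genes per barcode and the untreated capture 1056. Hashtags were assigned with HTODemux of Seurat 5.3.0 in R 4.3.3 at a positive quantile of 0.99, from the 2 hashtags of each capture. In the untreated capture it called 2417 barcodes BFP+ (28.7%), 907 BFP− (10.8%), 61 doublets and 5037 negative (59.8%). In the MC903 capture it called 1798 BFP+ (31.9%), 2542 BFP− (45.1%), 152 doublets and 1144 negative (20.3%). Of the untreated BFP+ calls, 588 had at least 80% of their hashtag counts from the BFP+ hashtag and 278 from the BFP− hashtag, and the rest were mixed. Only singlets entered the population sums. On 3000 simulated barcodes at each of 2 background levels, 97.1% and 97.9% of the called singlets carried their true label, and 71.7% and 82.1% of the true singlets were called. Those backgrounds (means of 5 and 30 counts) lie below the untreated capture, where BFP+ calls held a median of 74 counts of the other hashtag, so the simulation does not give the accuracy of those calls.

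Cells of both captures were clustered together, without batch correction, in Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2 and igraph 0.11.9. Counts were scaled to 10000 per cell and log-transformed. Of 2000 variable genes, ranked within each capture, 1926 were used after leaving out Tnfsf4, BFP and mitochondrial, ribosomal, immunoglobulin, T cell receptor and sex-linked genes. The neighbour graph used 30 principal components and 15 neighbours, and the Leiden resolution was 0.8. A cluster was named when at least 3 markers of a fixed list were at 20 CPM or more and 2 times their level elsewhere. A further condition, added after the clusters were seen, asked for at least 1 marker among the 10 leading genes. It left cluster 18 (with Cd24a, Prnp and Il1r2) unnamed, which held 0.470% of untreated BFP+ DCs, 0.915% of untreated BFP− DCs, 0 MC903 BFP+ DCs and 0.516% of MC903 BFP− DCs. The erythroid list was not used for naming. Clusters of other lineages were left out of the comparisons, and a cluster counted as another lineage when its best list was of that lineage with at least 3 markers, named or not. All other clusters, unnamed ones included, were kept as DCs.

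UMIs were summed over the DCs of each population and scaled to CPM. Log2 ratios have exact 95% intervals for 2 Poisson counts, which cover counting error only. A gene with 0 UMIs on one side was given as a bound, with 3 counts in place of 0. Genes counted as apart had at least 20 CPM in the higher population and a 1.5-fold ratio. With 1 pool per population no test was run, and such counts describe these libraries. In counts simulated as independent Poisson draws, between 94.9% and 95.6% of intervals held the true ratio, and at least 99.5% of 200 genes set 2-fold apart passed the 1.5-fold rule. The intervals assume such draws, so this checks the calculation and does not cover UMIs that gather in a few cells. For each of 17 gene lists and 16 marker lists written before the data were examined, the median log2 ratio of members with at least 50 UMIs is given with its percentile among 10000 random lists matched on expression, as a description of these libraries. Shares of cells have exact Clopper-Pearson intervals. Shares with a UMI of a gene were taken after thinning each cell to 2000 UMIs, and shares of clusters and cell types count all cells without thinning.

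Named genes were picked by rank. Eligible genes had at least 20 CPM in the higher population of each comparison used, and mitochondrial, ribosomal, immunoglobulin, T cell receptor, haemoglobin and sex-linked genes and unnamed gene models were left out. For the reporter contrast the 12 genes each way with the largest smaller log2 ratio of the 2 captures were named, and for treatment the 12 each way by the smaller ratio of BFP+ and BFP− cells. The 5 genes each way whose reporter contrast differed most between captures were named, as were 5 each way within the largest named DC class, and Tnfsf4 with 2 to 4 members of each list with the largest ratios. Genes named for a statement about a cluster or cell type are in addition to these. Coordinates are from the GENCODE M21 annotation of GRCm38 by Ensembl identifier.

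The alternatives were hashtag assignment by the dominant hashtag, at least 1000 genes, at most 5% mitochondrial UMIs, all singlets kept, TMM scaling with edgeR 4.0.16 (factors 1.01, 1.07, 0.943 and 0.978), the mean over cells in place of the sum, no CPM minimum, at least 100 CPM, Leiden resolutions 0.4 and 1.2, and each capture clustered alone. Scrublet, run in scanpy with 8% expected doublets, set thresholds that called 0 untreated barcodes and 1 MC903 barcode, so removing its calls moved nothing. After this was seen it was replaced by leaving out the 674 and 451 barcodes with the highest scores. At least 4000 UMIs and leaving out cluster 16 were also added after the data were seen. Numerical work used numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.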

Results

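Single-cell RNA sequencing measured the transcripts of migratory dendritic cells (DCs) in lymph nodes draining the ear. The mice were heterozygous for a reporter allele of Tnfsf4, the gene of the costimulatory ligand OX40L, that makes blue fluorescent protein (BFP). Their ears were left alone or received MC903 (calcipotriol, a vitamin D analogue that induces the cytokine TSLP in skin) on days 0, 2 and 4, and nodes were taken on day 5. From each treatment, 5000 BFP+ and 7000 BFP− cells were sorted on absent B220, intermediate CD11c and high MHC class II, stained with different hashtag antibodies, and loaded together. The study therefore has 4 populations in 2 captures, 1 pool of cells per population, and each capture gave a gene expression library and a hashtag library.

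The untreated capture held 9520 barcodes and 33525154 UMIs (unique molecular identifiers, 1 per captured transcript), with a median of 2520 per barcode. The MC903 capture held 6316 barcodes and 57148072 UMIs, with a median of 8562. After filtering, 8422 and 5636 barcodes remained. Hashtags assigned 2417 untreated barcodes to BFP+ and 907 to BFP−, and left 59.8% of the barcodes without a label. The unlabelled ones held a median of 180 counts of the BFP− hashtag and 8 of the BFP+ hashtag, whereas every BFP− call held at least 316 of the BFP− hashtag. In the MC903 capture, 1798 were BFP+, 2542 were BFP− and 20.3% had no label. Comparisons between populations used the cells in DC clusters. These were 1703 untreated BFP+ cells (7190351 UMIs, median 3017), 765 untreated BFP− cells (6552988, median 8320), 1498 MC903 BFP+ cells (16456288, median 10245) and 2325 MC903 BFP− cells (24710729, median 9822). By the dominant hashtag, 434 untreated DCs were BFP+ and 4101 were BFP−, the latter with a median of 2708 UMIs. The untreated BFP− population compared here is thus a deep subset of the DCs with mostly that hashtag. With 1 pool per population no difference has a replicate check and no test was run. The 95% intervals cover counting error only, and log2 ratios are of UMI counts in the summed cells, scaled to a common total (CPM).

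The first question was whether the sorted reporter followed its own gene. Tnfsf4 (ENSMUSG00000026700, GRCm38 chromosome 1, 161395409 to 161418410) was higher in BFP+ than in BFP− DCs in both captures. In the untreated capture it was at 22.3 CPM against 1.83, a log2 ratio of 3.60 (interval 2.76 to 4.59). In the MC903 capture it was at 32.5 CPM against 3.97, a log2 ratio of 3.04 (2.72 to 3.36). The BFP transcript differed in the same direction, at 67.0 against 1.53 CPM in untreated cells and 106 against 8.74 CPM after MC903. Between captures, Tnfsf4 was higher after MC903 in BFP+ cells by a log2 ratio of 0.55 (0.29 to 0.81), which was 0.20 when cells were assigned by their dominant hashtag, and in BFP− cells by 1.11 (0.25 to 2.12, from 12 untreated UMIs). Only clusters 2 and 3 had at least 100 BFP+ cells of each capture. Inside them Tnfsf4 in BFP+ cells was not higher after MC903, at −0.20 (−0.58 to 0.19) and −0.36 (−1.92 to 1.36). The ratio over all BFP+ DCs may therefore reflect the mix of clusters.

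Few cells carried a Tnfsf4 UMI, so the shares were compared at equal depth. Among DCs thinned to 2000 UMIs, 3.08% of untreated BFP+ cells and 5.25% of MC903 BFP+ cells had at least 1 Tnfsf4 UMI (exact intervals 2.27 to 4.07 and 4.17 to 6.50), with 177 and 11 shallower cells left out. In BFP− cells the thinned shares were lower, at 0.403% (0.083 to 1.17) and 0.563% (0.300 to 0.960), with 20 and 15 left out. Without thinning the shares were 6.34% and 16.7% in BFP+ cells and 0.915% and 2.97% in BFP− cells. B cell-like cells, which served as the background, had a Tnfsf4 UMI in 0 of 94 thinned untreated cells (median depth 3540 before thinning) and 0 of 374 after MC903 (median 3135), which leaves upper limits of 3.85% and 0.981% that are set by the number of cells. T cell-like cluster 12 had 0 of 124 and 0 of 257. The BFP− shares and the untreated BFP+ share lie under the limits of the B cell-like cells, although the untreated BFP+ share lies above that of BFP− DCs. By CPM of all their UMIs the limits were 9.40 and 2.71, which the BFP+ populations exceeded in both captures (18.9 to 26.0 and 29.8 to 35.4). BFP− DCs after MC903 (3.22 to 4.83) lay above the B cell-like limit but not above the interval of cluster 12 (0.360 to 5.10), and untreated BFP− DCs (0.946 to 3.20) lay above neither.

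**Figure D1:**
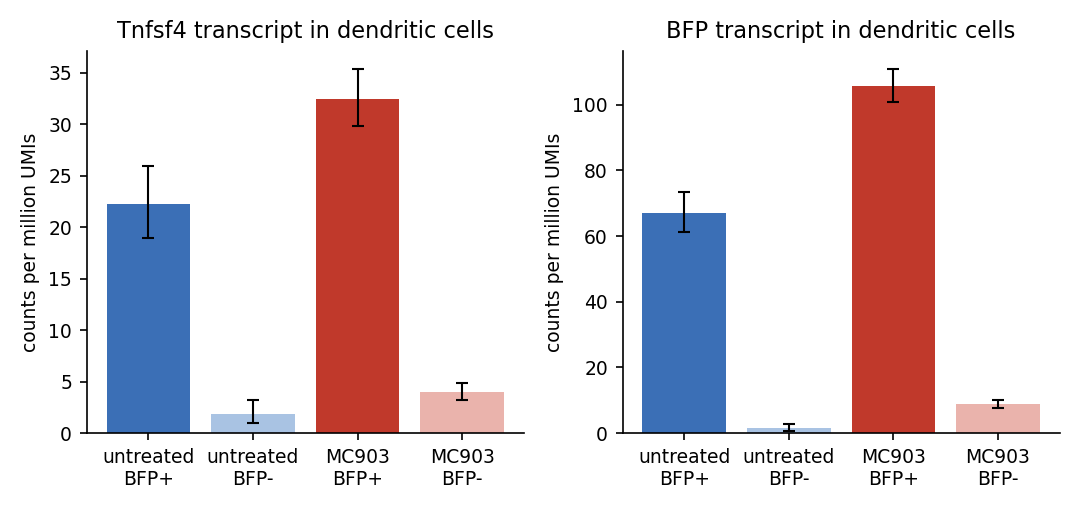
Level of the Tnfsf4 transcript (left) and of the BFP reporter transcript (right) in the summed DCs of each sorted population, in CPM; bars start at 0 and lines are exact Poisson 95% intervals, which cover counting error only. Tnfsf4 lay at 22.3 and 32.5 CPM in the BFP+ populations and at 1.83 and 3.97 CPM in the BFP− populations.

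The comparison of BFP+ with BFP− cells within each capture asked what distinguishes DCs that express OX40L. MHC class II genes were higher in BFP+ DCs in both captures. The list's median log2 ratio was 0.70 in untreated cells (12 of 13 genes measured, 9 of them at least 1.5-fold higher and 1 lower) and 0.76 after MC903 (11 measured, 9 higher and 0 lower). Both medians were at percentile 100 of 10000 random lists of matched expression. Ciita, the master transactivator of these genes (chromosome 16), was at 101 against 45.3 CPM in untreated cells (log2 ratio 1.16, 0.96 to 1.36) and at 160 against 74.4 CPM after MC903 (1.11, 1.02 to 1.19). H2-DMb2, H2-DMa and H2-Oa encode chains of H2-DM and H2-O and lie on chromosome 17 between 34092340 and 34151555. Their log2 ratios were 1.31, 0.88 and 1.01 in untreated cells and 1.11, 1.16 and 1.2 after MC903. The abundant H2-Aa was at 6030 against 3422 CPM and at 7033 against 4165 CPM.

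Markers of B cells moved with this group. Their list median was 1.97 in untreated and 0.75 in MC903 cells (5 of 10 genes measured in each). B cells also express MHC class II, and B220+ cells were excluded by the sort. The B cell transcript Cd79a was at 24.9 CPM in untreated BFP+ DCs and 5.19 CPM in untreated BFP− DCs, against 2881 CPM in the B cell-like cluster. After MC903 it was at 3.77 and 2.99 CPM.

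Other genes higher in BFP+ DCs of both captures were Dkk2, a secreted Wnt antagonist (1.63 untreated and 1.28 after MC903), Nrg1, a growth factor of the EGF family (1.40 and 1.22), Fam169b (1.83 and 1.07), Ly86, the MD-1 partner of RP105 (1.09 and 1.06), the phospholipase gene Pla1a (1.95 and 1.03), the cyclin gene Ccnd2 (1.71 and 0.94) and Atp1b1 (1.55 and 0.88). Dkk2, Nrg1 and Pla1a also lead a DC cluster that held 32.4% of MC903 BFP+ DCs and 16.2% of MC903 BFP− DCs. Costimulatory and checkpoint ligands had medians of 0.44 and 0.40 (11 of 14 genes measured, both at percentile 100), with 4 genes at least 1.5-fold higher and 1 lower in untreated cells and 1 and 1 after MC903. Cd80 was higher by 1.2 (1.03 to 1.38) in untreated cells and 0.40 (0.35 to 0.46) after MC903, Cd70 by 1.13 and 0.68, and Cd200 by 0.92 and 0.50. Inside clusters after MC903, Cd200 was near 0 in clusters 2 (−0.04), 6 (−0.03) and 10 (0.03) and higher only in cluster 3 (0.51, 0.13 to 0.89). The list of TSLP receptor and STAT5 target genes had a median of 0.28 in untreated cells (percentile 100, 4 of 14 genes higher and 0 lower) and 0.07 after MC903 (percentile 97.8, 1 higher and 0 lower). Within it Il2ra, the interleukin-2 receptor alpha chain, was higher by 1.05 (0.83 to 1.27) and 0.64 (0.55 to 0.74), and Crlf2, the TSLP receptor chain, was at −0.19 (−0.46 to 0.09) and −0.01 (−0.20 to 0.18). T cells also express Il2ra, Cd200 and Cd70, and the T cell markers had a median of 0.74 in untreated cells (percentile 100, 7 of 11 genes higher and 2 lower) and −0.06 after MC903.

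BFP− DCs had more inflammatory cytokine and chemokine transcripts. The list's median was −0.38 in both captures, at percentiles 0.04 and 0.01, with 3 of 13 measured genes at least 1.5-fold lower in untreated BFP+ cells and 5 of 16 after MC903, and 1 higher in each. The untreated median was 0.11 when all singlets were kept. Immediate early and dissociation genes, a sign of handling, were lower in untreated BFP+ cells too, with a median of −0.43 (4 of 14 at least 1.5-fold lower, percentile 0). Il1b was at 434 against 866 CPM in untreated cells (interval of the log2 ratio −1.06 to −0.93) and at 291 against 509 CPM after MC903 (−0.85 to −0.76). Ccl5, the most abundant of the named chemokines, was at 7965 against 14822 CPM and at 4851 against 9339 CPM. Cxcl9 went the other way in untreated cells, at 36.2 against 13.7 CPM.

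The genes lowest in BFP+ DCs of both captures largely matched 2 clusters that these cells seldom joined. Laptm4b (−1.53 untreated and −1.64 after MC903), Smagp (−1.46 and −2.60), Asprv1 (−1.41 and −2.44), Apol10b (−0.90 and −2.10), Dnase1l3 (−1.11 and −1.37) and Gclc (−1.07 and −1.73) lead cluster 8, and Xlr (−1.08 and −2.40) and Mfge8 (−1.08 and −1.37) lead the Langerhans cell-like cluster. Ttc39b was at −0.93 and −1.2. The rule also picked Bpifa2 and Smr3a, transcripts of salivary glands, whose untreated ratios of −6.04 and −4.20 rested mainly on 1 barcode: without the cluster that these genes lead they were 0.86 and 0.18.

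The reporter contrast was alike in both captures across genes. The Spearman correlation of the log2 ratios was 0.554 over 5209 genes, which are not independent replicates, and 70.6% had the same direction. Of 4469 eligible genes, 36 were at least 1.5-fold higher and 39 lower in both. Within a capture, 116 of 5062 genes were at least 1.5-fold higher in untreated BFP+ cells and 174 lower (40% of those apart were higher), and 62 of 4783 were higher and 95 lower after MC903 (39.5%). Scaling by TMM moved these splits to 157 and 103 (60.4%) and to 80 and 78 (50.6%), so the balance of higher and lower genes depends on the scaling.

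**Figure D2:**
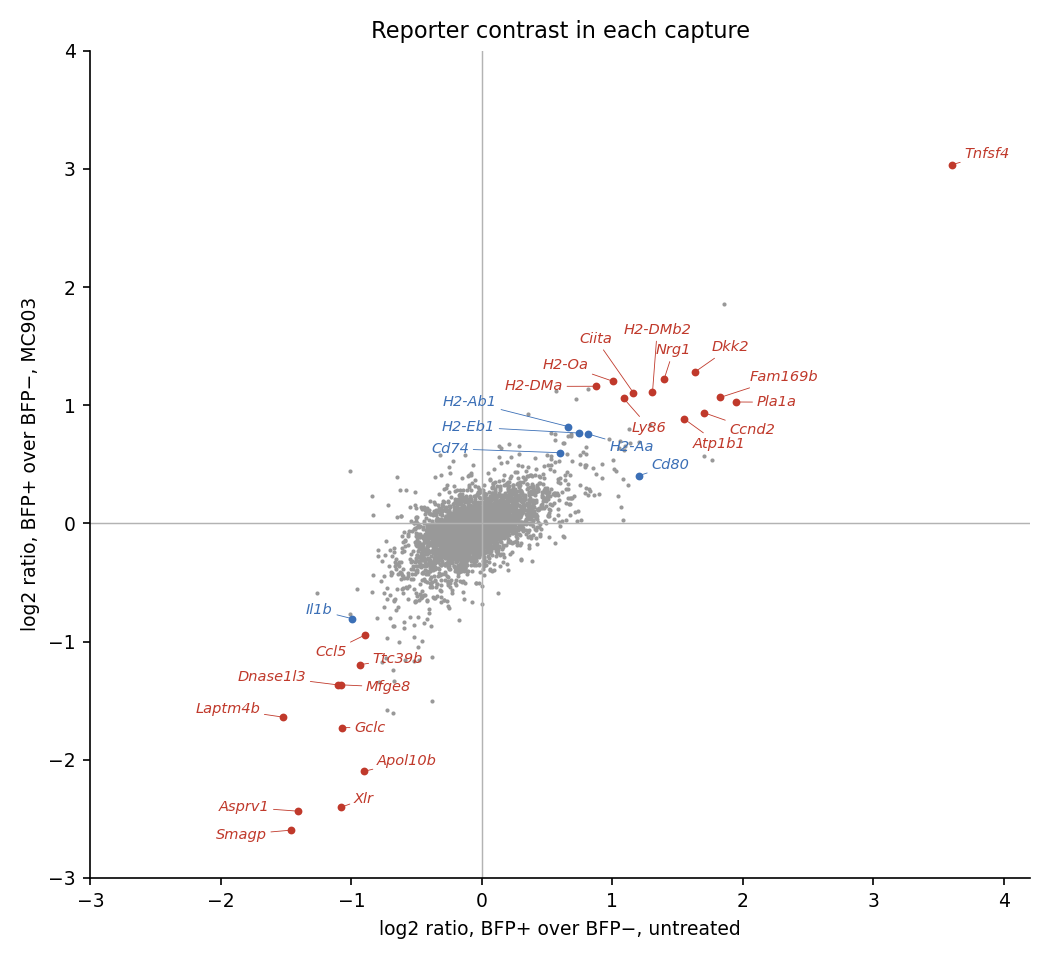
Log2 ratio of BFP+ to BFP− DCs for each gene in the untreated capture (horizontal axis) and the MC903 capture (vertical axis), for 4631 genes at 20 CPM or more in the higher population of each capture; red marks genes picked by rank in both captures, blue other genes of the text, and 4 genes (Amy1, BFP, Bpifa2 and Smr3a) lie outside the axes. Tnfsf4 stands at 3.60 and 3.04, MHC class II genes lie at the upper right and Ccl5 and Il1b at the lower left.

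Differences over all DCs can come from the mix of clusters, so the contrast was repeated inside clusters with at least 100 cells of each population. Tnfsf4 was higher in BFP+ cells of every such cluster with more than 3 UMIs in each group, by log2 ratios of 2.44 in cluster 1 of the untreated capture and of 2.57 and 2.44 in clusters 2 and 6 of the MC903 capture. In clusters 3 and 10 of the MC903 capture, with 3 UMIs each in BFP− cells, it was 2.36 (0.44 to 4.84) and 2.73 (1.07 to 5.07). Ciita was higher by 2.45 (1.85 to 3.12) in cluster 1 and 2.99 (2.07 to 4.05) in cluster 3 of untreated cells. In that cluster 1, 1022 BFP+ cells held 3435619 UMIs and 252 deeper BFP− cells 1790982. The contrasts inside clusters were not repeated at matched depth or with dominant hashtags. After MC903 Ciita was higher by 1.60 (1.31 to 1.90) in cluster 3 and 0.78 (0.51 to 1.06) in cluster 6. It was higher by only 0.37 (0.23 to 0.52) and 0.30 (0.11 to 0.50) in clusters 2 and 10. The abundant H2-Aa, H2-Eb1 and Cd74 were at 0.76, 0.76 and 0.60 over all DCs after MC903. They were at only 0.19, 0.10 and 0.12 in cluster 2 and 0.14, 0.07 and 0.13 in cluster 10. In clusters 3 and 6 they were at 1.18, 1.27 and 0.90 and at 0.51, 0.55 and 0.40. Part of their overall ratio after MC903 thus depends on the mix of clusters. Il1b was lower in clusters 1 (−1.61), 2 (−0.66), 3 (−0.82 untreated and −0.85 after MC903) and 6 (−1.25), and its interval included 0 in cluster 10 (−0.17, −0.57 to 0.23). Ccl5 was much closer inside clusters than over all DCs, at −0.12 in cluster 1 and −0.14 in cluster 3 of untreated cells, and at −0.43, −0.13, −0.04 and −0.19 in clusters 2, 3, 6 and 10 after MC903.

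Cell types were named from fixed markers, and most DCs stayed unnamed. Langerhans cell-like cells, led by Epcam among other genes, made up 13.7% of untreated BFP− singlets (exact interval 11.5 to 16.1) and 2.03% (1.5 to 2.67) of untreated BFP+ singlets. After MC903 they made up 14.2% (12.9 to 15.7) and 0.445% (0.192 to 0.875). With dominant hashtags the untreated BFP− share was 7.52% and the MC903 BFP+ share 0.117%, and the MC903 BFP− share was 8.98% with at most 5% mitochondrial UMIs. With each capture clustered alone, no MC903 cluster was named Langerhans cell-like. Because genes that lead this cluster, such as Xlr and Mfge8, are among the genes lower in BFP+ cells, the share and those ratios are the same observation. The depth gap between untreated BFP+ and BFP− cells applies to these shares. T cell-like cells made up 15.6% of untreated BFP+, 8.38% of untreated BFP−, 6.62% of MC903 BFP+ and 4.68% of MC903 BFP− singlets. Most of them lay in cluster 4 in untreated BFP+ cells (332 of 376) and in cluster 12 in the other populations (40 of 76, 87 of 119 and 76 of 119). Untreated cluster 4 held the DC transcript Fscn1 at 1485 CPM, against 1978 in DC clusters and 41.9 in cluster 12. Its Cd3e was at 74.1 CPM against 417 in cluster 12, and its Cd79a was at 217 CPM. The T cell-like share thus counts barcodes with DC and lymphocyte RNA, which were left out of the DC sums. B cell-like cells made up 1.12%, 1.43%, 7.95% and 1.46%, in the same order. These lymphocyte shares depend on the settings: the T cell-like share of untreated BFP+ cells was 6.37% at resolution 0.4, and the B cell-like share of MC903 BFP+ cells was 0.656% with at most 5% mitochondrial UMIs. All DC clusters together held 70.5%, 84.3%, 83.3% and 91.5% of singlets.

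**Figure D3:**
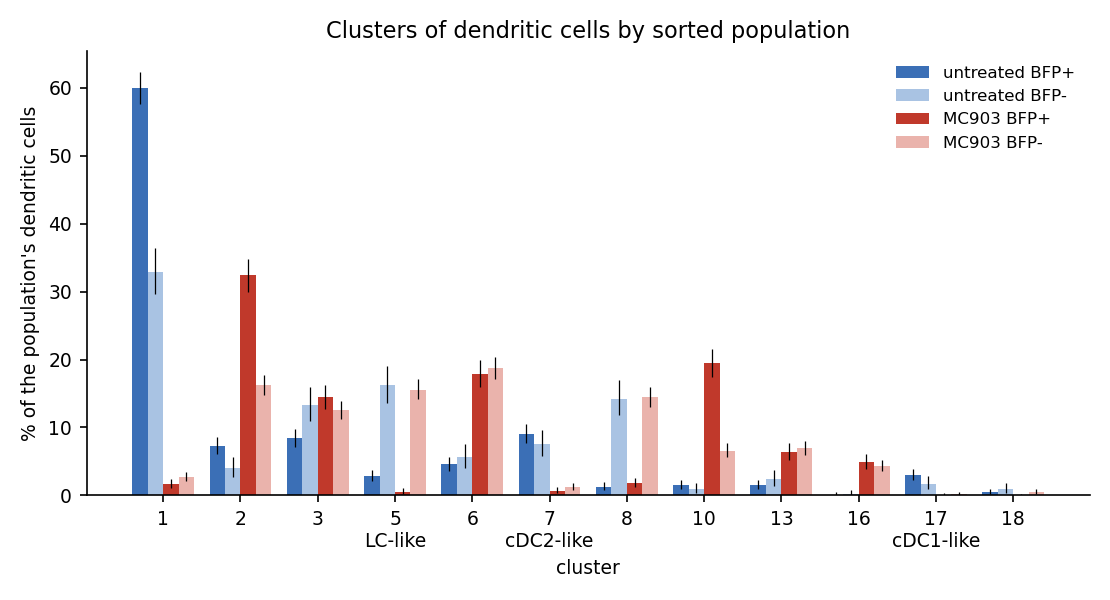
Percent of each sorted population's DCs in each DC cluster, with exact binomial 95% intervals that cover counting error only; clusters are in order of size, and names are given where the fixed markers allowed one (LC, Langerhans cell). Langerhans cell-like cells, whose leading genes are among those lower in BFP+ cells, held 16.2% and 15.6% of BFP− DCs and 2.88% and 0.534% of BFP+ DCs; clusters 1, 7, 17 and 18 are mostly of the untreated library and clusters 2, 6, 10, 13 and 16 mostly of the MC903 library, so their sizes are not compared between treatments. With dominant hashtags the untreated BFP+ and BFP− shares of clusters 1, 3, 6, 7, 13 and 17 were in the opposite order; cluster 1 went from 60.0% against 32.9% to 34.3% against 51.4%.

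The comparison of MC903 with untreated DCs asked what TSLP-inducing treatment does to each population. The treatment is the same split as capture, library and sequencing lane, so these cannot be told apart. Cish, a STAT5 target that restrains cytokine signalling, was at 35.4 against 4.73 CPM in BFP+ DCs (log2 ratio 2.91, 2.41 to 3.45) and at 31.6 against 3.05 CPM in BFP− DCs (3.37, 2.74 to 4.09). Its list had medians of 0.42 and 0.48 over 14 genes, both at percentile 100, but its members went both ways: 2 were at least 1.5-fold higher and 3 lower in BFP+ cells, and 4 and 2 in BFP− cells. Socs1, Socs2 and Socs3, also feedback inhibitors, were higher by 0.53, 0.41 and 0.57 in BFP+ cells and 0.58, 0.54 and 0.49 in BFP− cells, whereas Pim1 was at −0.67 and −0.45 and Bcl6 at −0.91 and −0.77. The T cell markers, which show lymphocyte RNA, moved the opposite way, with medians of −2.79 and −2.0 over 10 measured genes.

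Costimulatory and checkpoint ligands were higher after MC903, with medians of 0.69 in BFP+ and 1.10 in BFP− DCs (percentile 100 in both). Of 11 measured genes 6 were at least 1.5-fold higher in each population, and 1 and 3 were lower. Cd86 was higher by 1.46 (1.38 to 1.54) and 1.73 (1.63 to 1.83), Cd80 by 1.08 (0.98 to 1.18) and 1.88 (1.73 to 2.03), Pdcd1lg2, which encodes PD-L2, by 1.31 and 1.84, and Cd274, which encodes PD-L1, by 0.79 and 1.10. Icosl was lower, at −0.52 and −0.90. Inside cluster 2, BFP+ cells had no higher Cd80 after MC903 (−0.02, −0.19 to 0.15), whereas inside cluster 3 it was higher by 2.03 (1.46 to 2.64). Ccl17 and Ccl22, chemokines for CCR4-bearing T cells, were higher by 0.99 (0.92 to 1.06) and 0.96 (0.93 to 0.99) in BFP− cells and by 0.28 and 0.69 in BFP+ cells, although Ccl17 in BFP+ cells was at −0.04 with dominant hashtags. Their list of type 2-associated DC genes had medians of −0.35 and −0.47 (1 of 11 genes higher and 4 lower, and 3 of 12 higher and 6 lower), with Cd209a, a cDC2 marker, at −2.49 (−2.76 to −2.22) in BFP− cells.

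Inflammatory cytokine and chemokine genes were lower after MC903, with medians of −0.58 and −0.64 (percentile 0 in both; 6 of 13 genes at least 1.5-fold lower and 2 higher, and 9 of 15 lower and 2 higher). Monocyte and macrophage markers were lower in the same contrasts (−0.91 and −0.98), as were immediate early and dissociation genes in BFP− cells (−0.58, 7 of 14 at least 1.5-fold lower). In BFP+ cells the immediate early and dissociation genes had a median of −0.11, with 1 gene at least 1.5-fold higher and 0 lower. Cxcl2 was at 22.0 against 74.3 CPM in BFP+ cells and 37.2 against 98.3 CPM in BFP− cells, Tnf at −0.96 and −0.97 and Ltb at −1.02 and −1.07, while Cxcl10 was higher by 0.90 and 1.06. Il1b, lower over all DCs by −0.58 and −0.77, was instead higher inside cluster 2 of BFP+ cells (0.65, 0.46 to 0.83) and inside the Langerhans cell-like cluster (0.48, 0.24 to 0.72) and cluster 8 (0.52, 0.22 to 0.83) of BFP− cells, and lower inside cluster 3 of BFP− cells (−0.52, −0.93 to −0.10), so its overall ratio depends on the mix of clusters. MHC class II genes had medians of 0.23 and 0.22 (2 of 11 genes higher and 0 lower, and 3 of 12 higher and 1 lower), with Ciita higher by 0.66 and 0.72. Inside cluster 2, BFP+ cells had less Ciita after MC903 (−0.50, −0.70 to −0.29), whereas inside cluster 3 it was higher in BFP+ (0.73, 0.36 to 1.11) and BFP− cells (2.11, 1.23 to 3.15). The vitamin D receptor gene Vdr was higher by 1.93 (1.47 to 2.43) and 2.28 (1.64 to 2.99). The vitamin D list was near the detection limit, and its 3 measured genes of 7 were Vdr, Rxra (−0.43 and −0.97) and Cd14 (−1.19 and −2.13). Its median is therefore that of Rxra and rests on few UMIs, and in BFP+ cells it was 0.67 with dominant hashtags.

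Among the genes picked by rank, the higher ones outside these lists were Thy1, which encodes a glycoprotein also found on T cells (2.58 in BFP+ and 3.19 in BFP− cells), Mylk, the myosin light chain kinase (2.76 and 2.47), and the interferon-inducible Ifitm1 (2.17 and 2.15). The lower ones were Itgb8, the integrin chain that activates TGF-beta (−4.39 and −2.93), the epithelial transcription factor gene Ehf (−3.26 and −2.50), Mpeg1 (−3.11 and −1.74), Clu, which encodes clusterin (−2.68 and −2.49), Fxyd2 (−2.60 and −2.13), the growth factor gene Csf1 (−2.30 and −1.97), the chemokine gene Cxcl1 (−2.28 and −1.87), Ms4a6c (−2.23 and −2.85), Lrmp (−2.02 and −2.10), Plbd1 (−1.83 and −2.34), Cd209d (−1.81 and −2.21, but 0.026 in BFP+ cells with dominant hashtags) and M1ap (−1.81 and −1.77). Thy1 leads cluster 2 and Ifitm1 cluster 8. Cxcl1, Fxyd2, Ehf, Clu and M1ap lead cluster 1, and Ms4a6c, Plbd1 and Cd209d lead the cDC2-like cluster 7. Plbd1 and Mpeg1 also lead the cDC1-like cluster 17, and cDC1 markers were lower in the same contrasts (−1.34 and −1.55). Clusters 1, 7 and 17 held 3175 of 3282, 770 of 821 and 208 of 216 barcodes from the untreated capture and may be that library. Clu and Itgb8 were lower inside the Langerhans cell-like cluster too, and Clu inside clusters 2, 3 and 8.

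The other 8 of the 12 genes ranked highest after MC903 were Smr3a, Chia1, Car6, Dnase1, Cst10, Bpifa2, Pip and Amy1, which salivary glands express. Bpifa2 was at 1215 against 2.92 CPM in BFP+ DCs and at 2736 against 192 CPM in BFP− DCs. Of the MC903 capture's UMIs of 20 salivary genes listed, 85.6% lay in 3 barcodes. With cluster 16, which these genes lead, left out, Bpifa2 was still higher by 4.64 and 5.61, and the genes that then took the free ranks were Pla1a, Htr7, Ccnd2, Hopx, Stxbp6 and Pkib (log2 ratios 1.5 to 2.03 in BFP+ and 1.56 to 2.95 in BFP− cells), named after their values were seen.

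The treatment contrasts of BFP+ and BFP− cells had a Spearman correlation of 0.770 over the same 5209 genes. In BFP+ cells 207 of 4918 genes were at least 1.5-fold higher and 220 lower (48.5% higher), and in BFP− cells 247 of 5089 were higher and 310 lower (44.3%). TMM scaling moved the splits to 316 and 165 (65.7%) and to 393 and 201 (66.2%), and the median log2 ratio of all genes from −0.02 to 0.08 and from −0.06 to 0.08. The groups named above kept their direction under that scaling.

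Langerhans cell-like cells were the largest named DC class, and only the BFP− populations had enough of them to compare (362 after MC903 and 124 untreated). Cd80 was higher after MC903 by 2.62 (1.94 to 3.39), Cd274 by 2.46 (1.92 to 3.05), Cd86 by 1.74 (1.48 to 2.02) and Cish by 2.64 (0.70 to 5.73, from 2 untreated UMIs). The highest ranked genes were Tmem246 (4.57, 2.06 to 9.89, from 1 untreated UMI), Ccnd2 (3.32, 2.38 to 4.46) and Coro2a (2.94, 1.78 to 4.40), besides Bpifa2 and Smr3a, which had no untreated UMI and were higher by at least 4.06 and 3.79 on the log2 scale. The lowest were Pkp1 (−3.32), Clu (−3.15), Evl (−2.96), Itgb8 (−2.93) and Phf11d (−2.74).

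A last comparison asked which genes had a different reporter contrast in the 2 captures. Stat4, the transcription factor downstream of interleukin-12, was higher in BFP+ cells by 1.76 (1.56 to 1.96) in the untreated and by 0.54 (0.48 to 0.60) in the MC903 capture, and Hopx by 1.71 (1.25 to 2.19) and 0.57 (0.46 to 0.68). T cells express Stat4, and the T cell markers had medians of 0.74 and −0.06 in the same contrasts. Hilpda, a hypoxia-induced lipid droplet gene, and Cd8a had opposite signs in the captures. Xlr, Apol10b and Smagp were lower in BFP+ cells of both captures and more so after MC903. The salivary genes Amy1, Bpifa2 and Smr3a differed most, and their untreated values rested mainly on 1 barcode. No test of these differences was possible with 1 pool per population.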

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

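The list of salivary genes was written after the leading genes of cluster 16 had been seen, and the tests of salivary expression by DCs in general, of cluster 4 in the untreated capture and of wrong hashtag labels were chosen only after their results had been seen.

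The genes and lists here had a BFP+ against BFP− ratio of opposite sign in the captures, and the difference between captures was not tested. Hilpda was at 0.44 after MC903 and −1.01 in untreated cells. Cd8a was at 0.23 and −0.84, but at −0.09 after MC903 with dominant hashtags. Interferon-stimulated genes had a median of 0.19 after MC903 (14 of 16 genes measured, percentile 99.8) and −0.18 in untreated cells (10 measured, percentile 13.9). Cholesterol synthesis genes were at −0.31 (16 genes, percentile 0) and 0.05 (percentile 94.5; −0.13 with dominant hashtags), with Sqle at −0.57 and −0.31. Immediate early and dissociation genes were at 0.040 (14 genes, percentile 91.4; −0.05 with dominant hashtags) and −0.43 (percentile 0), with Jun at 0.58 and −0.13 and Egr1 at 0.06 and −0.65.

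Data outside the comparisons also held signals. DC barcodes without a hashtag call had the BFP transcript at 10.5 CPM in the untreated capture and 16.7 CPM in the MC903 capture, above the 1.53 and 8.74 CPM of BFP− calls. In the MC903 capture, the 2 hashtags used only for untreated cells made up 0.20% of hashtag counts, spread over 4336 barcodes, against 0.00578% for the MC903 hashtags in the untreated capture.

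Among the genes ranked, which leave out haemoglobin genes, transcripts of salivary glands were furthest apart between MC903 and untreated DCs. RNA freed from a few gland cells stays open as their source. Against it were Lpo (88 UMIs in DCs outside cluster 16 and 1 in B and T cell-like cells) and Dcpp1 (92 and 0). At 2000 UMIs, a Bpifa2 UMI was 1.51 times as frequent in B and T cell-like cells as in DCs outside cluster 16 (interval 1.22 to 1.85; 13.0% of 631 and 8.59% of 4468 cells, 34 and 46 left out; 17.7% and 24.7% before thinning, at median depths of 3565 and 9850). That ratio cannot decide, since cluster 16, where 207 of 218 thinned cells had a Bpifa2 UMI, was left out of the DCs only. A ratio with cluster 16 kept among the DCs was not computed. The shares do show that Bpifa2 UMIs were not limited to DC barcodes. As the source of most salivary UMIs, expression by DCs in general is argued against, since 85.6% of the capture's 201726 salivary UMIs lay in 3 barcodes. The first had 125370 of its 162867 UMIs from these genes. That share is set by those barcodes, so it does not address low-level expression by DCs. The most abundant salivary transcripts were Bpifa2 (96356 UMIs), Smr3a (61087) and Amy1 (16808). The sort on intermediate CD11c and high MHC class II would remove gland cells, and no biological explanation was tested.

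Cluster 4 carries DC and lymphocyte transcripts in the same barcodes and holds most T cell-like cells of the untreated BFP+ population. In the untreated capture, doublets of a DC and a lymphocyte as the source of most of its barcodes are argued against by its median depth, 0.868 times that of DCs (0.844 to 0.893), and a smaller part stays open. In the MC903 capture they stay open. There, 11.2% of its barcodes (5.52 to 19.7) were hashtag doublets against 2.79% of DCs, the lower limit being less than double. The median depth of its 89 barcodes there was 12978 UMIs against 9824 in DCs, a ratio of 1.32, which goes with doublets. No biological explanation was tested.

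Of the untreated BFP+ calls among DCs, 197 carried mostly the BFP− hashtag. That all of them are BFP− cells with a wrong label is argued against by their BFP transcript at 37.3 CPM (24.4 to 54.7), against 1.53 CPM in BFP− calls and 80.3 CPM in BFP+ calls with mostly the BFP+ hashtag. A mislabelled part stays open, and the 1075 calls with mixed hashtags had 61.6 CPM. How such labels would change the untreated reporter contrast was not tested. The 197 calls had a median of 3085 UMIs and the BFP− calls 8320, so the 2 groups also differ in depth. No biological explanation was tested.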

How the results depend on the processing

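The alternatives chosen only after the data were seen were at least 4000 UMIs, the highest Scrublet scores removed, and without cluster 16. Across the alternatives, 2963 of 2988 ratios of named genes, 547 of 576 list medians and all 36 of 36 ratios of Tnfsf4 kept their sign. Size was less stable than sign for single genes. Of the 2988 ratios 531 were counted as moved, as were 5 list medians and 1 ratio of Tnfsf4. With dominant hashtags 145 ratios of named genes moved, 1 reversed and 186 stayed the same. Most of the ratios and medians that changed sign were near 0 at first. Exceptions were Ccl17 and Irf4 in BFP+ cells with treatment, which moved from 0.28 to −0.04 and from 0.32 to −0.10 with dominant hashtags. Of ratios at least 1.5-fold from 1 and of list medians in the outer percentiles, those reversed were the untreated inflammatory list (0.11 with all singlets kept), untreated Bpifa2 (0.86) and Smr3a (0.18) without cluster 16, Bpifa2 and Smr3a after MC903 (0.084 and 0.081 by the mean over cells), and Cd209d in BFP+ cells with treatment (0.026 with dominant hashtags). Dominant hashtags also moved the treatment ratio of Tnfsf4 in BFP+ cells from 0.55 to 0.20. Without a CPM minimum, the genes at least 1.5-fold apart went from 290 to 4055 and from 157 to 4309 in the reporter contrasts of untreated and MC903 cells, and from 427 to 4790 and from 557 to 5519 in the treatment contrasts of BFP+ and BFP− cells. The Spearman correlation of the reporter contrasts moved from 0.554 to 0.679 at 100 CPM or more, 0.531 with dominant hashtags, 0.533 with at most 5% mitochondrial UMIs, 0.531 with all singlets and 0.509 by the mean over cells. The share of all DC clusters in untreated BFP+ cells (70.5%) moved to 73.2% with dominant hashtags, 72.4% with at least 1000 genes, 75.6% with at most 5% mitochondrial UMIs, 78.7% and 68.6% at resolutions 0.4 and 1.2, 66.3% with each capture alone and 78.6% with at least 4000 UMIs. In untreated BFP− cells (84.3%) it moved to 71.7% with dominant hashtags, 92.2% with the mitochondrial limit and 86.7% with at least 4000 UMIs. In MC903 BFP+ cells (83.3%) it moved to 94.3% with the mitochondrial limit and 90.7% with at least 4000 UMIs. In MC903 BFP− cells (91.5%) it moved to 84.3% with dominant hashtags, 95.1% with the mitochondrial limit, 92.8% with the Scrublet scores, 90.3% with each capture alone and 93.0% with at least 4000 UMIs. The reporter part of the comparison within the largest named class was not run, since that class had too few BFP+ cells.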

Other observations

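In the reporter contrast, cDC1 markers were lower in BFP+ cells, with medians of −0.52 in untreated cells (4 of 9 genes at least 1.5-fold lower and 0 higher) and −0.99 after MC903 (5 of 8 lower and 0 higher), as were Langerhans cell markers (−0.86 and −0.73, with 4 lower in each and 0 and 1 higher). Those of cDC2 were at −0.36 (5 of 11 lower and 1 higher) and −0.06. Maturation and migration genes, which tell resting from migrating DCs, had medians of −0.03 in untreated cells and −0.10 after MC903 (16 genes), and Ccr7 was at 2607 against 2555 CPM in untreated cells. MHC class I presentation was at −0.15 and −0.16 (12 genes), the NF-kappaB pathway at −0.18 and −0.07 (14 genes), glycolysis at −0.11 and −0.10 (15 genes), the unfolded protein response at −0.12 and −0.11 (12 genes) and cell cycle genes at −0.28 and −0.06. Type 2-associated genes were at 0.07 and −0.09 and the vitamin D list at −0.62 and −0.08. Tolerance and retinoic acid genes had medians of 0.38 and 0.22 and went both ways, with 3 of 8 measured genes at least 1.5-fold higher and 1 lower in untreated cells and 2 of 10 higher and 3 lower after MC903. The lower ones after MC903 were Aldh1a2, which makes retinoic acid (−0.53 untreated and −0.87), Itgb8 (−0.76 and −2.22) and Ido1 (−0.87 after MC903). No gene of the sex-linked list was measured, so the sex of the mice was not checked.

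In the treatment contrast, in BFP+ and then BFP− cells, maturation and migration genes were at 0.04 and 0.10, MHC class I at −0.07 and 0.02, the NF-kappaB pathway at 0.08 and −0.05, glycolysis at −0.05 and 0.09, the unfolded protein response at −0.16 and −0.15, and cell cycle genes at −0.21 and −0.36. Interferon-stimulated genes were at 0.35 and −0.19, with Isg15 higher by 1.11 and 0.97. Cholesterol synthesis genes were at 0.00 and 0.15, immediate early genes at −0.11 and −0.58, and tolerance genes at 0.41 and 0.39, with Aldh1a2 at −1.51 and −1.17. Markers of cDC1 were lower after MC903, at −1.34 and −1.55, as were those of monocytes and macrophages, at −0.91 and −0.98, and of cDC2, at −0.27 and −0.29. Langerhans cell markers were lower in BFP− cells (−0.90), but at −0.11 in BFP+ cells (percentile 30.5, 2 of 6 genes at least 1.5-fold lower and 0 higher). B cell markers were lower in BFP+ cells (−1.16), but at −0.40 in BFP− cells (percentile 33.8, 1 of 4 genes higher and 1 lower). Haemoglobin Hbb-bs was at 98.5 CPM in untreated BFP+ DCs (708 UMIs) and 0.31 CPM in untreated BFP− DCs (2 UMIs).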
